A study of Mus musculus with 20 samples.

How the data were processed

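RNA-seq was analysed from the frontal cortex of 5-month-old C57BL/6 mice with 0, 1 or 2 copies of a knock-in allele of Tardbp, the gene of the RNA-binding protein TDP-43, that carries the protein change Q331K. The samples were 6 wild-type, 6 heterozygous and 8 homozygous libraries, grouped by the labels. Per the labels' protocols, stranded libraries were made from polyadenylated RNA. Per the submitters' processing notes, Trim Galore 0.4.3, HISAT2 2.0.5 and the genome build GRCm38 were used. The counting program, its annotation and its strand setting are not given in the sources used here, so overlapping genes on opposite strands are named where a value could be shared. The labels give separate samples of each genotype and nothing more, so p-values measure the spread between these samples.

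The deposited values were raw whole-number counts per gene, not normalised, in 1 table of 25965 rows. Of these, 56 named rows had no gene identifier, held at most 0.0835% of the counts of any library and were kept, and 124 rows that shared a name were kept apart. Totals ran from 61282647 to 111440766 counts per library. Odd values made up 73.9% to 76.6% of the counts from 1 to 10, and at means of 2 to 10 the median ratio of variance to mean was 2.1 to 2.19 by genotype. That ratio also holds the spread between samples, so whether a sequenced fragment was counted more than once is not known. No libraries were identical, and the smallest chi-square per degree of freedom among 58 pairs within genotypes was 13.0. Of 25909 identifiers, 24990 (96.5%) were matched to GENCODE M21, which was used for overlaps between genes, and coordinates are those of the deposited table.

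Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust dispersions, quasi-likelihood test), with the 20 libraries in 1 fit by genotype. Genes with low counts were removed by filterByExpr, which left 16690 genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over these genes. The trend used the number of Q331K alleles as a number, and the midpoint contrast set heterozygotes against the mean of the other genotypes. Levels are CPM, counts scaled to library size with TMM factors, and log2 changes are edgeR's. Gene lists were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with an inter-gene correlation preset at 0.01, and again with the correlation estimated, and adjusted over the 34 lists tested of 35. The list left out held sex chromosome genes and served as a check. List scores are mean z scores of log2 CPM, compared by two-sided exact permutation tests.

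The groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took Tardbp, the 10 raised and 10 lowered genes of smallest p among those called with a mean of at least 1 CPM in homozygous against wild type, 5 and 5 in the other comparisons, and up to 4 members of a described list. Predicted genes and clone names were passed over and counted. Single genes of the cholesterol synthesis list are not reported here. The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, a filter of 1 CPM in 6 libraries, the replicate number as a block, 3 surrogate variables (sva 3.50.0), limma voom with quality weights, fits of only the 2 genotypes compared, each library left out in turn and a length limit of 200 kb. Alternatives that left out libraries by their ependymal score, used tissue scores as covariates or halved the counts, and 4 gene lists, were chosen after the data were seen.

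The fit was tested on simulated counts with 200 changed genes among 16690 in each of 5 runs. For homozygous against wild type, 48.8% of changes of 0.2 on the log2 scale, 75.2% of 0.3 and 92.4% of 0.5 were recovered, and 3.6% of calls were false. Simulated heterozygotes lay at the midpoint. For heterozygous against wild type, 1.6%, 12.8% and 54.8% of the genes with those homozygous changes were recovered, and for homozygous against heterozygous 4%, 18% and 61.6%. For the trend, 48.8% of the genes with a homozygous change of 0.2 were recovered. Departures of 0.2 from the midpoint, simulated separately, were recovered in 57.2% of cases. Of the simulated lists, 1 shifted list of 12 genes was called and 0 of 20 unchanged lists. Genes were drawn independently and the lists at random, so these simulations hold no shared variation between genes. They do not show how often lists or genes are called falsely where genes vary together.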

Results

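The frontal cortex transcriptome of mice at 5 months of age was measured in 6 wild-type libraries and in 6 heterozygous and 8 homozygous for the TDP-43 Q331K allele. Library totals ran from 75168829 to 96821696 counts in wild type, from 61282647 to 111440766 in heterozygotes and from 69312426 to 105412832 in homozygotes. Mitochondrial transcripts took 8.69 ± 1.72% of counts in wild type (SD, n = 6), 8.15 ± 1.39% in heterozygotes (SD, n = 6) and 7.66 ± 1.01% in homozygotes (SD, n = 8). Xist, which overlaps Tsix on the opposite strand, lay at or below 0.148 CPM and the Y-linked gene Ddx3y at or above 39.5 CPM in each library.

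Tardbp, the edited gene, was higher in homozygotes. TDP-43 is known to limit the level of its own mRNA. The gene lies on chromosome 4 from 148612382 to 148627019 on the minus strand (GRCm38) and overlaps Masp2 on the opposite strand. Its level was 218 ± 5.53 CPM in wild type (SD, n = 6), 230 ± 7.58 CPM in heterozygotes (SD, n = 6) and 245 ± 10.5 CPM in homozygotes (SD, n = 8). Homozygotes exceeded wild type by 0.17 on the log2 scale with a standard error of 0.029 (edgeR adjusted p = 0.00372), and a two-sided exact permutation test gave p = 0.000333, the smallest that its 3003 splits can give. The log2 difference of heterozygotes from wild type was 0.08 (exact permutation p = 0.0195) and did not pass adjustment over all genes. The homozygous call was lost with ependymal, olfactory and meningeal scores as covariates, at a log2 change of 0.16 (adjusted p = 0.0577, edgeR). It was also lost without 9 libraries of high ependymal score, at 0.12 (adjusted p = 0.266, edgeR), a fit that keeps 2 homozygous libraries. Without the 4 libraries with a score over 0.5 the call was kept, at 0.15.

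The first comparison asked which genes differed when both alleles carried the change. Among the genes lowered in homozygotes, Spop, a substrate adaptor of a ubiquitin ligase, went from 179 ± 4.58 CPM in wild type (SD, n = 6) to 154 ± 2.71 CPM in homozygotes (SD, n = 8), a log2 change of -0.22. Nefh, the heavy neurofilament subunit of large axons, went from 90.5 ± 4.19 CPM (SD, n = 6) to 73.9 ± 3.26 CPM (SD, n = 8), a log2 change of -0.29 with a standard error of 0.040 (edgeR adjusted p = 0.000264). Among the raised genes, D2hgdh, which codes for a mitochondrial dehydrogenase, went from 7.58 ± 0.560 CPM (SD, n = 6) to 10.2 ± 0.397 CPM (SD, n = 8), a log2 change of 0.42 with a standard error of 0.048 (edgeR adjusted p = 1.65e-05). In all, 107 genes were raised and 154 lowered of 16690 tested. Changes were small: the median absolute log2 change of called genes was 0.23, and 8 genes exceeded 1.

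Other lowered genes were Dus2l, a tRNA dihydrouridine synthase, which fell by 0.45 on the log2 scale, Kirrel2, an adhesion molecule, which fell by 0.48, and Stat6, a transcription factor of interleukin signalling, which fell by 0.37. Afg3l1, a mitochondrial protease gene, fell by 0.27, Ociad2 fell by 0.27 and Acad8, an enzyme of valine breakdown, fell by 0.29. The olfactory receptor gene Olfr316 fell by 0.91 from 2.15 ± 0.275 CPM in wild type (SD, n = 6), and the immunoglobulin constant gene Ighg2c fell by 0.66 from 5.64 ± 0.499 CPM (SD, n = 6). Both belong to multigene families whose members can share reads, so their values are uncertain. The same holds for Dus2l, which overlaps Dpep2 and Ddx28, and Stat6, which overlaps Nab2, on opposite strands, and for Afg3l1, which overlaps Gm20388 on the same strand. Raised genes included Synrg, which acts in membrane traffic, at a log2 change of 0.20, the kinase of the Hippo pathway Lats1 at 0.18, Meaf6 at 0.15, the growth factor Ptn at 0.16, and Cpne1 at 0.15, which overlaps Nfs1 and Rbm12 on the same strand.

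Sox4, a transcription factor of immature neurons, rose by 0.35 on the log2 scale, the secreted Wnt modulator Sfrp1 by 0.36 and the noncoding RNA Dlx6as1 by 0.35. Dlx6as1 overlaps Dlx6os2 and Dlx6as on the same strand and Dlx6 on the opposite strand, so its value is uncertain. The score of ependymal and motile cilia genes, a list chosen after the data were seen, was 0.45 ± 0.854 in homozygotes (SD, n = 8) and -0.51 ± 0.230 in wild type (SD, n = 6), with an exact permutation p of 0.0157. The list was not called with an estimated correlation (p = 0.0593). Of the genes passed over as predicted or clones, 11 were raised and 15 lowered. One of them, chosen after its values were seen because its p was the smallest of the comparison, was 4933439F18Rik, listed as Gid4 in GENCODE M21. It fell by 0.49 on the log2 scale (edgeR adjusted p = 3.24e-09) and overlaps Atpaf2 on the opposite strand.

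The number of called genes was 29 without the 9 libraries of high ependymal score, which keeps 2 homozygous libraries, and 253 without the 4 with a score over 0.5. The number was 114 with the tissue scores as covariates, 102 with surrogate variables and 634 with DESeq2. It was 139, 148, 122 and 115 without wild-type replicates 1, 3, 5 and 6 in turn, and 147 without homozygous replicate 5.

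**Figure D1:**
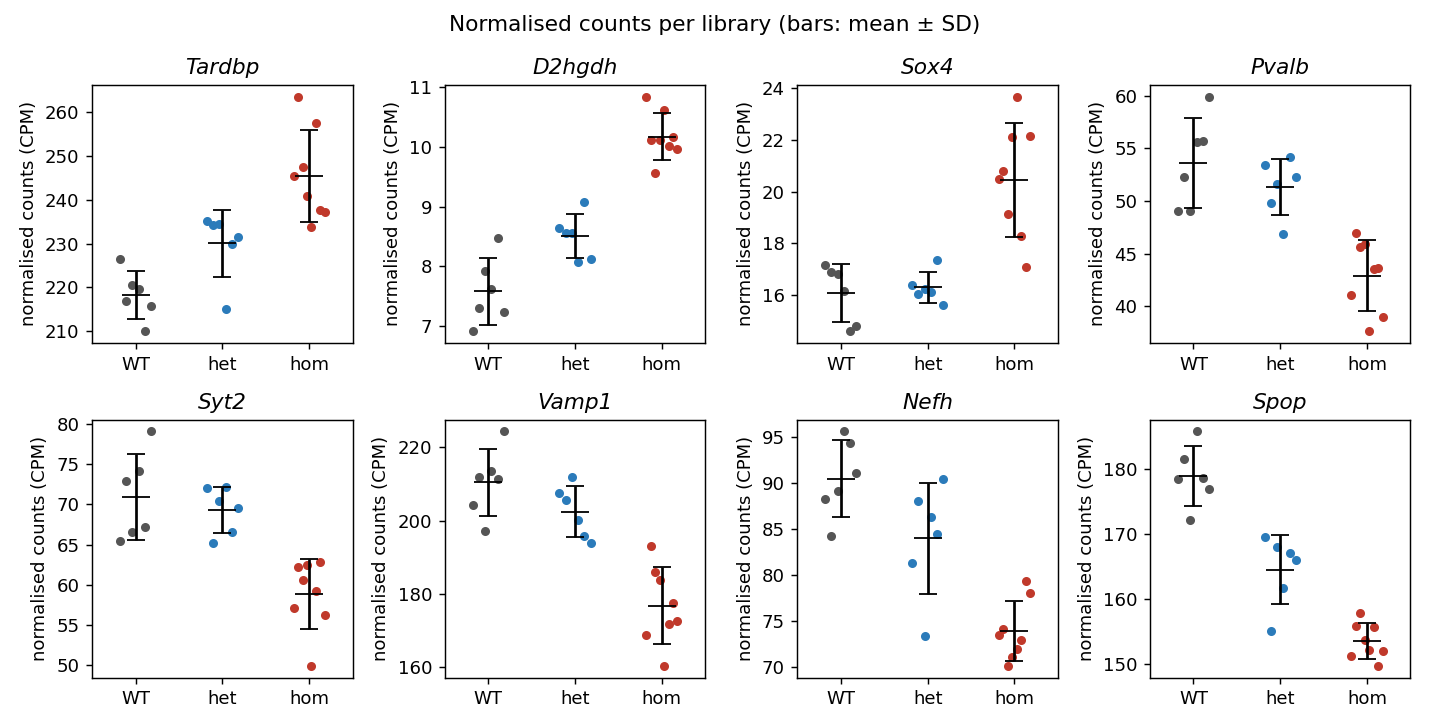
Normalised counts in CPM (vertical axes, not starting at 0) of single genes in each library of the wild-type (WT, n = 6), heterozygous (het, n = 6) and homozygous (hom, n = 8) groups, with points for libraries and bars for the mean and SD. Tardbp rose from a mean of 218 CPM in wild type to 245 CPM in homozygotes, and Spop went from 179 to 154 CPM.

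Markers of parvalbumin interneurons, the fast-spiking inhibitory cells of cortex, were lower in homozygotes than in wild type. Each of the 12 listed genes had a negative estimate, with a median log2 change of -0.15. Pvalb, the calcium-binding protein that names the cells, went from 53.6 ± 4.27 CPM (SD, n = 6) to 42.9 ± 3.40 CPM (SD, n = 8), a log2 change of -0.32. Syt2 and Vamp1, which act in fast transmitter release, had log2 changes of -0.27 and -0.25, and Cox6a2, a subunit of cytochrome oxidase, of -0.41. These 4 genes were called over all genes, and 9 of the 12 when adjusted over the list alone. Vamp1 overlaps Tapbpl and Cd27, and Cox6a2 overlaps Itgad, on opposite strands. The list score was 0.59 ± 0.328 in wild type (SD, n = 6) and -0.67 ± 0.411 in homozygotes (SD, n = 8), and the highest homozygous library, at -0.18, lay below the lowest wild-type library, at 0.22. The list was called with an estimated correlation (camera, adjusted p = 0.0229) and in the exact permutation test (adjusted p = 0.0113 over 34 lists).

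The lists of the other neurons, of myelin, astrocytes and microglia, and of genes linked to TDP-43 and splicing were not called. Of 24 GABAergic interneuron markers, Pvalb was the 1 called gene, and 3 were raised and 4 lowered when adjusted over the list alone. Excitatory neuron markers had a median log2 change of -0.02, with Cux1 called lowered (-0.16) of 22 genes and 1 when adjusted over the list alone. Cux1 overlaps Gm16599 on the opposite strand and A430110C17Rik on the same strand. Of 17 microglia markers Fcrls was called lowered (-0.24), and 1 when adjusted over the list alone. None of the 20 myelin genes and 16 astrocyte markers was called over all genes by edgeR, and adjusted over the list alone 0 myelin genes, 2 raised and 7 lowered astrocyte markers were called. Among 33 genes linked to amyotrophic lateral sclerosis and frontotemporal dementia, Nek1 (-0.14) and Vapb (-0.11) were called lowered, and the same number when adjusted over the list alone. Nek1 overlaps Gm16178 on the opposite strand. None of 24 genes with TDP-43-dependent levels or splicing in other work was called by edgeR either way, and the list's median log2 change was -0.0089 where its mean was 0.01. Counts per gene do not show which exons are used, so a change in the splicing of these genes was not tested. None of 66 splicing factors and hnRNP proteins was called either way.

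With the preset correlation 11 of the 34 lists were called, 3 up and 8 down, while other splits of the same 14 libraries called a median of 10 lists. The unfolded protein and integrated stress response list had a median log2 change of -0.15, with Herpud1, which overlaps Gm15890 on the opposite strand, called over all genes (-0.21) and 4 lowered when adjusted over the list alone (camera p = 0.0295 and adjusted p = 0.501 with an estimated correlation). Oxidative phosphorylation genes of the nucleus had a median of -0.05 and 0 called genes either way (p = 0.127 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.04, with Rps15a called over all genes and when adjusted over the list alone (p = 0.402 with an estimated correlation). Clock genes had a median of -0.10, 0 genes called over all genes and 1 when adjusted over the list alone (p = 0.102 with an estimated correlation). Cholesterol synthesis genes had a median of -0.05 (p = 0.249 with an estimated correlation). Presynaptic genes had a median of -0.016, with Vamp1 and Syt2 called over all genes and 4 when adjusted over the list alone (p = 0.248 with an estimated correlation). The direction of the presynaptic list turned, to a median change in log2 CPM of 0.0032 with surrogate variables, 0.016 with the tissue scores as covariates, 0.026 without the 9 libraries of high ependymal score and 0.0091 without the 4 with a score over 0.5. That of the clock list turned without the 9 libraries, to 0.014. Proteasome and autophagy genes had a median of -0.025 and 0 called genes either way (p = 0.341 with an estimated correlation).

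The lists called up held markers of neighbouring tissue and receptors. Meningeal and fibroblast genes had a median log2 change of 0.32, 0 genes called over all genes and 3 when adjusted over the list alone (p = 0.13 with an estimated correlation). Choroid plexus genes had a median of 0.51, 0 genes called over all genes and 1 when adjusted over the list alone (p = 0.076 with an estimated correlation). The choroid plexus median turned to -0.0071 with surrogate variables and to -0.018 with the tissue scores as covariates. Glutamate receptors had a median of 0.06 and 0 called genes either way (p = 0.133 with an estimated correlation).

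**Figure D2:**
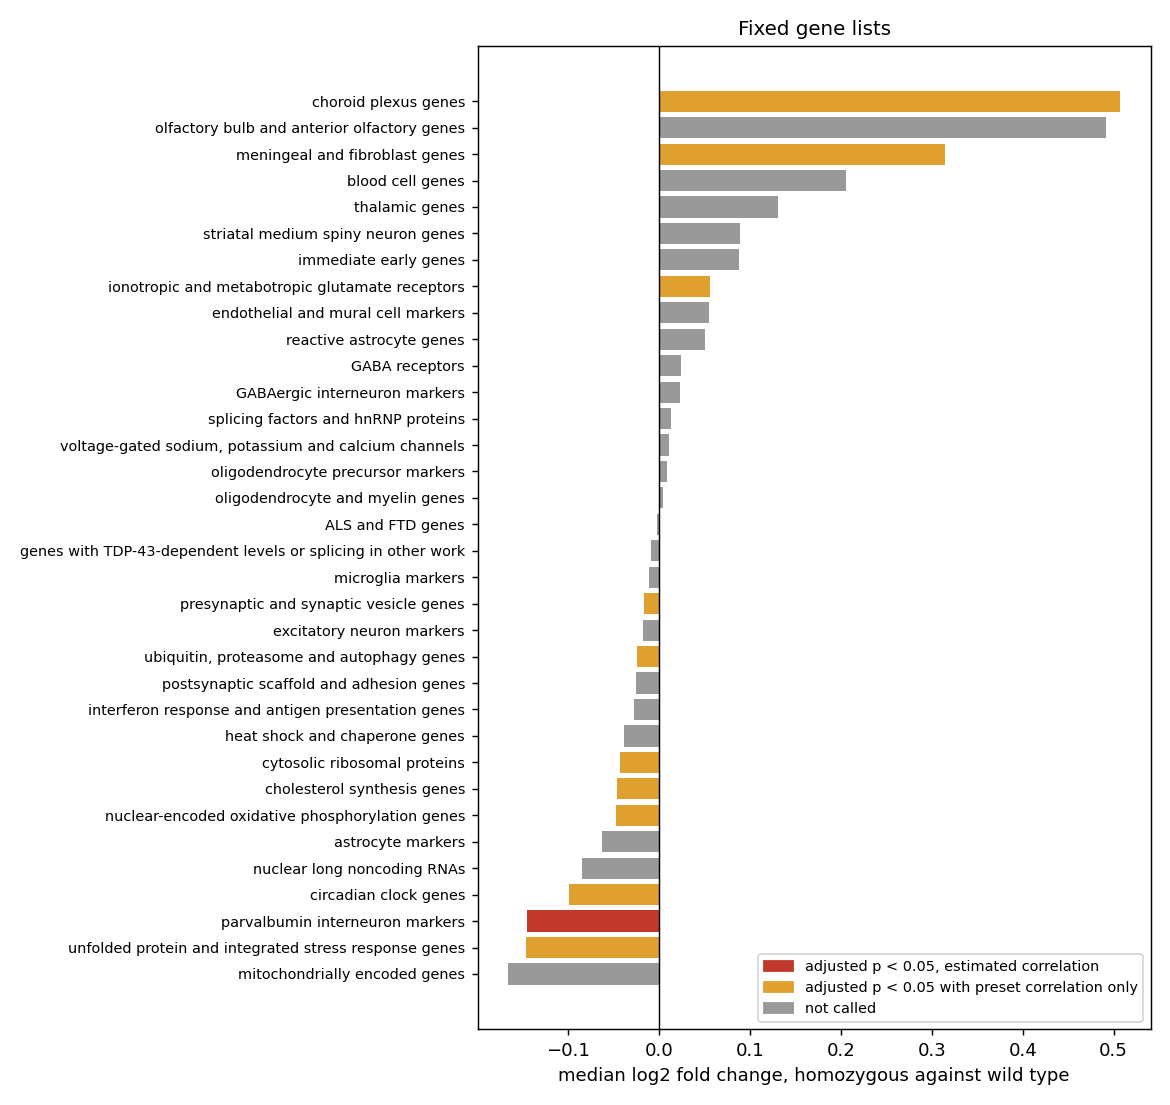
Median log2 fold change of homozygotes against wild type (horizontal axis, bars from 0) for 34 gene lists, coloured by whether a list was called with an estimated correlation, with the preset correlation alone, or not. The parvalbumin list, at -0.15, is the 1 list called with an estimated correlation.

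**Figure D3:**
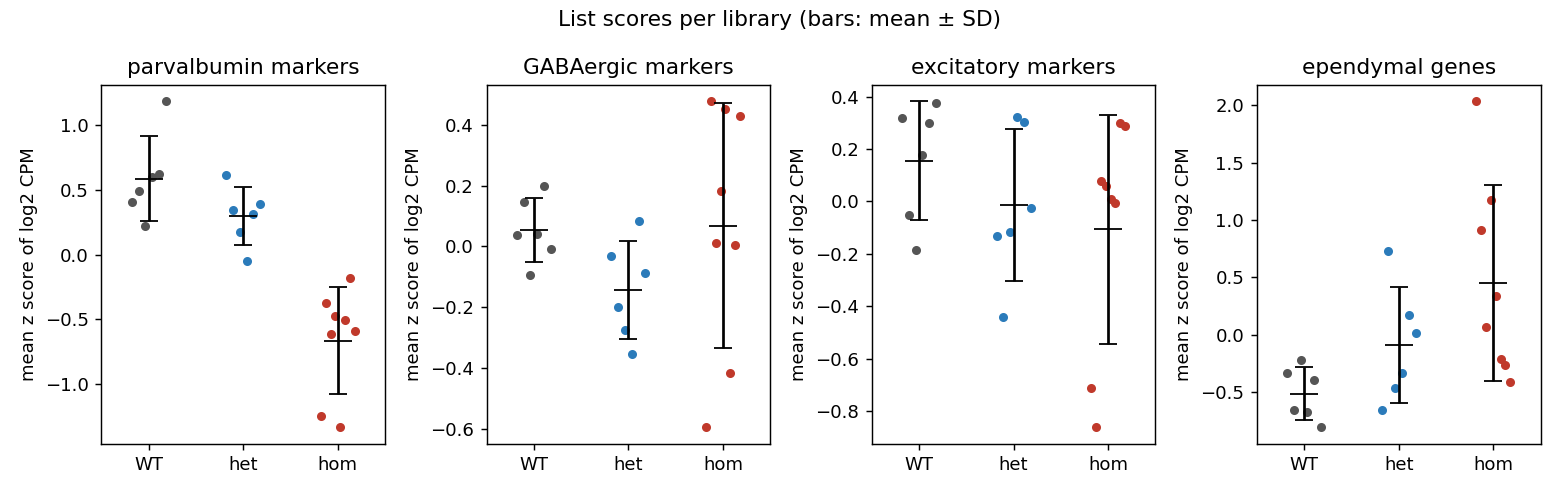
Mean z score of log2 CPM (vertical axes) of gene lists in each library of the wild-type (WT, n = 6), heterozygous (het, n = 6) and homozygous (hom, n = 8) groups, with points for libraries and bars for the mean and SD. For the parvalbumin list the homozygous libraries lie at or below -0.18 and the wild-type libraries at or above 0.22.

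Genes of at least 100 kb were compared with the others, since TDP-43 is known to bind long introns and its loss to lower long genes. The 2283 long genes had a median log2 change of 0.02 in homozygotes and the 14407 others of -0.0027, with 29 long genes raised and 20 lowered. The list was called up, not down, with the preset correlation (camera p = 0.00232), and the call was lost with an estimated correlation (p = 0.0967).

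Heterozygotes were compared with wild type to ask what 1 changed allele did. Pvalb was 51.4 ± 2.66 CPM in heterozygotes (SD, n = 6), Nefh 84.0 ± 6.06 CPM and Spop 164.5 ± 5.34 CPM, and none of them was called by edgeR. By edgeR 0 genes were called, with 532 at an unadjusted p under 0.05 where 834 are expected by chance, and DESeq2 called 2 and limma voom 0. The parvalbumin list had a median log2 change of -0.04 and was not called. Striatal medium spiny neuron genes had a median of 0.34 and 0 called genes by edgeR over all genes or when adjusted over the list alone (p = 0.202 with an estimated correlation), and their score was 3.09 in heterozygous replicate 1. The other lists called with the preset correlation were, with their p with an estimated correlation, myelin genes up (p = 0.489), and down the proteasome and autophagy (p = 0.0994), oxidative phosphorylation (p = 0.375), presynaptic (p = 0.184), unfolded protein response (p = 0.129) and heat shock genes (p = 0.225). Each of these had 0 genes called by edgeR over all genes and when adjusted over the list alone, and other splits called a median of 7 lists, the number called here. The direction of the myelin list turned with surrogate variables (-0.038) and with the tissue scores (-0.0033), and without the 9 libraries so did that of the proteasome and autophagy (0.0015) and oxidative phosphorylation lists (0.0044).

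Homozygotes were compared with heterozygotes to ask what the second changed allele added. Sox4 rose by 0.33, Ptn by 0.16, D2hgdh by 0.26 and Meaf6 by 0.12 on the log2 scale. Kirrel2 fell by 0.43, Dus2l fell by 0.32, Acad8 fell by 0.25, Rmnd1, which overlaps Gm16153 on the opposite strand, fell by 0.25, and Vamp1 fell by 0.20. In all 5 genes were raised and 13 lowered. Pvalb (-0.26), Syt2 (-0.24) and Vamp1 were the called parvalbumin markers over all genes, and 9 were called when adjusted over the list alone. That list had a median log2 change of -0.14 (camera adjusted p = 0.052 with an estimated correlation, exact permutation adjusted p = 0.0113). The count of called genes was 5 without heterozygous replicate 2, homozygous replicate 1 or homozygous replicate 8, 10 and 7 without heterozygous replicates 3 and 6, 11 without homozygous replicate 6, 29 without wild-type replicate 6 and 31 without homozygous replicate 2. It was 1 with surrogate variables, 10 with the tissue scores as covariates, 102 with DESeq2 and 0 by edgeR without the 9 libraries of high ependymal score, which keeps 2 homozygous and 3 heterozygous libraries.

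With the preset correlation 14 lists differed between homozygotes and heterozygotes, where other splits called a median of 10. The count was 8 with the replicate block and 7 without homozygous replicate 8. Lists called up, with their p with an estimated correlation, were meningeal (p = 0.15), choroid plexus (p = 0.128), olfactory bulb (p = 0.212) and glutamate receptor genes (p = 0.12). With surrogate variables the meningeal (-0.011), choroid plexus (-0.094) and olfactory medians (-0.086) turned negative, and the choroid plexus median also did with the tissue scores (-0.11), without the 9 libraries (-0.29) and without the 4 (-0.016). The olfactory score was 1.83, 1.61 and 1.23 in homozygous replicates 8, 5 and 2, and 0.243 to -0.624 in the others. Lists called down besides the parvalbumin list, with their p with an estimated correlation, were cytosolic ribosomal (p = 0.386), oxidative phosphorylation (p = 0.29), astrocyte (p = 0.31) and clock genes (p = 0.12). So were, with their p with an estimated correlation, unfolded protein response (p = 0.15), interferon response (p = 0.306), nuclear long noncoding RNA (p = 0.12), cholesterol synthesis (p = 0.353) and myelin genes (p = 0.527). Without the 9 libraries the clock (0.021), unfolded protein response (0.079) and nuclear long noncoding RNA medians (0.018) turned positive. None of these lists held a gene called by edgeR over all genes, and when adjusted over the list alone 5 olfactory genes were raised, 1 astrocyte marker was raised and 6 lowered, and 2 clock genes were lowered.

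Over 0, 1 and 2 Q331K alleles 130 genes rose and 176 fell. D2hgdh rose by 0.21 per allele on the log2 scale, Synrg by 0.10, Lats1 by 0.09, Sfrp1 by 0.18 and Dlx6as1 by 0.18. Spop fell by 0.11 per allele, Dus2l fell by 0.23, Olfr316 fell by 0.46, Afg3l1 fell by 0.14 and Ighg2c fell by 0.34. The count of called genes was 159 without wild-type replicate 5 or 6 and 189 without homozygous replicate 5. It was 99 with surrogate variables or with the tissue scores as covariates and 692 with DESeq2. Without the 9 libraries of high ependymal score, which keeps 2 homozygous and 3 heterozygous libraries, it was 18. Without the 4 with a score over 0.5 it was 193. No gene departed from the midpoint of wild type and homozygotes by edgeR, with 573 at an unadjusted p under 0.05, and DESeq2 called 1 and limma voom 0.

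Of the 261 genes called in homozygotes, 248 (95.02%) had the same sign in heterozygotes, and both comparisons used the same wild-type libraries. The median ratio of the heterozygous to the homozygous log2 change was 0.35, and 203 of the 261 genes lay nearer to wild type than to homozygotes. These genes were chosen by their homozygous change and the wild-type libraries are shared, so the ratio is a description and not a test of the midpoint. With simulated unchanged heterozygotes the share was 64.5% (56.9% to 71.1%) where the homozygous changes were kept, and 94.5% (92% to 96.9%) for the genes of smallest p where neither genotype was changed, over 20 simulations each. With the wild-type libraries split into 3 and 3 it averaged 90.4%, from 77.01% to 98.9% over 20 assignments. That share is of the 261 genes, which were chosen with all wild-type libraries. For the genes that each assignment called it averaged 76.9%, from 36.8% to 100%. The assignment with the most calls, 382 genes, gave 41.1%, and that with the fewest, 16 genes, gave 100%. How far the sign is shared thus depends on the assignment. The covariance of the log2 changes was 0.019, against 0.0128 simulated with neither genotype changed and 0.00411 with the wild-type libraries split.

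**Figure D4:**
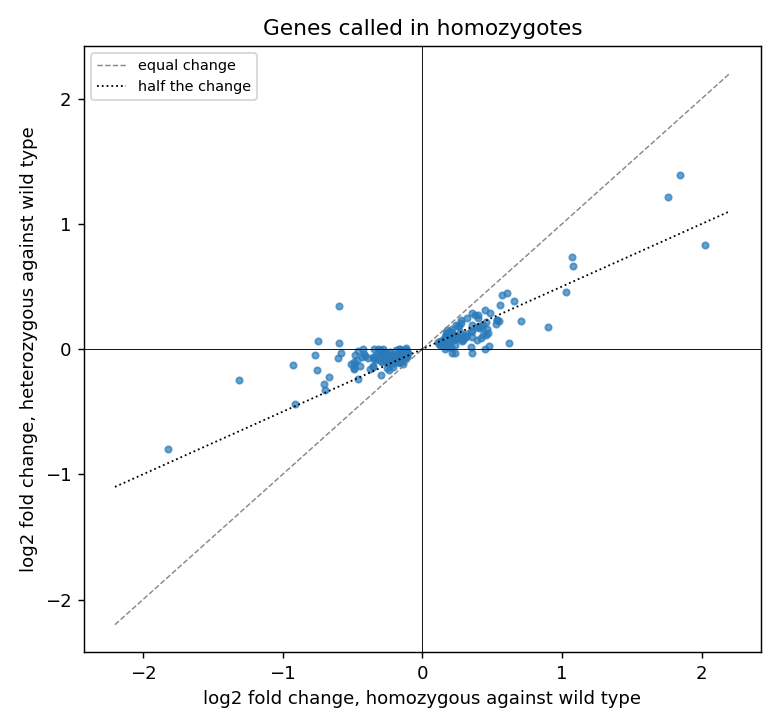
Log2 fold change of heterozygotes (vertical axis) against that of homozygotes (horizontal axis), both against wild type, for the 261 genes called in homozygotes (points), with lines for an equal change and for a heterozygous change at the midpoint. Of these genes 248 share their sign, and the wild-type libraries are shared by both axes.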

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

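No test in this part was chosen after its result was seen. Single libraries were compared with the rest of their genotype in 186 sets of values, and 9 lay far from the others, where chance gives about 9.3. Tardbp was 215 CPM in heterozygous replicate 4, against 230 to 235 CPM in the other heterozygotes. Afg3l1 was 15.9 CPM in homozygous replicate 5, against 17.3 to 18.4 CPM in the other homozygotes. Rmnd1 was 37 CPM in heterozygous replicate 6, against 31.8 to 33.6 CPM. Heterozygous replicate 1 had a striatal score of 3.09, against -0.607 to 0.402, and a clock gene score of 0.527, against 0.029 to 0.161. Wild-type replicate 1 had a postsynaptic score of 0.899, against -0.145 to 0.204, and a channel gene score of 0.505, against -0.17 to 0.016. The splicing factor score was -0.408 in heterozygous replicate 4, against -0.091 to 0.072, and the cytosolic ribosomal score was -0.514 in wild-type replicate 4, against 0.103 to 0.444.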

How the results depend on the processing

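The tests that left out libraries by their ependymal score, used tissue scores as covariates or halved the counts were chosen after the data were seen, and the second ependymal rule after the result of the first. Counts of called genes are given for homozygous against wild type, homozygous against heterozygous and the trend in this order, where 261, 18 and 306 were called. Surrogate variables gave 102, 1 and 99, the tissue scores as covariates 114, 10 and 99, and DESeq2 634, 102 and 692, and the cause was not tested. Without the 9 libraries with an ependymal score above every wild-type library the counts were 29, 0 (edgeR) and 18. That fit keeps 2 homozygous and 3 heterozygous libraries, and how far fewer samples alone lower the counts was not tested. Without the 4 libraries with a score over 0.5 the counts were 253, 21 and 193. No filter gave 11 genes for homozygous against heterozygous. Leaving out single libraries gave 115 to 314, 5 to 31 and 159 to 436. For heterozygous against wild type and for the midpoint, edgeR called 0 genes under each alternative and with each library left out, limma voom 0, and DESeq2 2 and 1. The log2 change of Tardbp was 0.1247 (adjusted p = 0.266, edgeR) without the 9 libraries and 0.1622 (adjusted p = 0.0577, edgeR) with the tissue scores, and 0.15 to 0.18 with single libraries left out. With an estimated correlation 1, 0 and 0 lists were called in homozygous against wild type, heterozygous against wild type and homozygous against heterozygous, and the median log2 CPM change of long genes, 0.02301, was no longer called (p = 0.0967). Leaving out single libraries gave 10 to 16, 5 to 9 and 7 to 16 lists, the lowest being 7 without homozygous replicate 8, and 0.01548 to 0.02882 for long genes. The replicate numbers did not pair the samples: 1 of 18 same-numbered pairs had a correlation over 0.1 (-0.104 to 0.139) and 4 of 18 libraries were closest to their own number. With the replicate block 387, 16 and 383 genes and, for homozygous against heterozygous, 8 lists were called. Median changes in log2 CPM of some lists took the other sign, and the cause was not tested. Only lists called in the main fit or the alternative are given. With surrogate variables these were, against wild type in homozygotes, choroid plexus (-0.007113), presynaptic (0.003163) and mitochondrially encoded genes (0.1668), in heterozygotes myelin genes (-0.03825), and in homozygous against heterozygous reactive astrocyte (-0.1812), meningeal (-0.01082), choroid plexus (-0.09406), olfactory (-0.08576), blood cell (-0.2351) and mitochondrially encoded genes (0.3548). Without the 9 libraries they were clock (0.01399) and presynaptic genes (0.02561) in homozygotes, cholesterol synthesis (0.03788), proteasome and autophagy (0.001523) and oxidative phosphorylation genes (0.004436) in heterozygotes, and in homozygous against heterozygous choroid plexus (-0.2931), blood cell (-0.5189), clock (0.02121), unfolded protein response (0.07913), proteasome and autophagy (-0.03087), postsynaptic (0.07161) and nuclear long noncoding RNA genes (0.01772). Without the 4 libraries they were presynaptic genes in homozygotes (0.009112) and, against heterozygotes, choroid plexus (-0.01598) and blood cell genes (-0.2463). With the tissue scores they were reactive astrocyte (-0.2002), choroid plexus (-0.01805) and presynaptic genes (0.01612) in homozygotes, myelin genes in heterozygotes (-0.003313) and, against heterozygotes, reactive astrocyte (-0.2111) and choroid plexus genes (-0.1123). Some of these lists were called in the alternative, with the preset correlation. With surrogate variables they were mitochondrially encoded, reactive astrocyte and blood cell genes. Without the 9 libraries they were cholesterol synthesis, blood cell, postsynaptic and, against heterozygotes, proteasome and autophagy genes. Without the 4 they were blood cell genes, and with the tissue scores reactive astrocyte genes. The parvalbumin list stayed called in homozygous against wild type under each alternative that tested lists. Besides the estimated correlation itself, these used the preset correlation, under which other splits called a median of 10 lists. DESeq2, limma voom, the other filters, the fits of 2 genotypes and the halved counts did not test lists. Values of single genes and lists were also sorted under the alternatives fixed in advance. Of them 3260 kept direction and call or were uncalled in both fits, whatever their sign. With the sign kept, 176 lost the call and 84 gained it, and 10 took the other sign with a call in either fit. Under the alternatives chosen later these numbers were 352, 59, 30 and 21. Halving the counts, in case fragments were counted more than once, gave 266, 12 and 318 genes. Genes of low level rest on few counts, such as the cilia gene Dnahc11, which overlaps Cdca7l on the opposite strand and averaged 0.285 CPM in wild type. How far depth limits their calls was not tested.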

Other observations

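The gene lists in this part, the tests on excitatory and GABAergic markers and the layer 4 list were chosen after the results were seen, and lists drawn up from called genes are not independent evidence of their direction. Glucocorticoid-induced genes were lower in homozygotes, with 7 of 27 called lowered and 15 when adjusted over the list alone, and a median log2 change of -0.28. Fam107a went from 626 ± 112 CPM in wild type (SD, n = 6) to 440 ± 60.5 CPM in homozygotes (SD, n = 8), Tsc22d3, a glucocorticoid-induced leucine zipper, from 82.7 ± 8.92 to 60.0 ± 10.5 CPM, and Klf15 from 26.0 ± 2.40 to 21.4 ± 1.77 CPM. The list gave p = 0.0143 with an estimated correlation and an exact permutation p of 0.00266. In heterozygotes its median was 0.0014.

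Genes of the subventricular neuroblasts and progenitors that line the ventricle were higher in homozygotes, with 6 of 26 called raised, 15 when adjusted over the list alone, and a median log2 change of 0.26 (p = 0.00095 with an estimated correlation, exact permutation p = 0.00133). Besides Sox4, Sfrp1 and Dlx6as1 these were Zic2, from 7.86 ± 1.10 CPM in wild type (SD, n = 6) to 10.5 ± 1.20 CPM in homozygotes (SD, n = 8), Pax6, which overlaps Pax6os1 and Elp4 on the opposite strand, and Mcm6. Ependymal and motile cilia genes had a median of 0.40, with 7 of 30 called raised and 16 raised and 1 lowered when adjusted over the list alone (p = 0.0593 with an estimated correlation, exact permutation p = 0.0157). Their score was above 1 in homozygous replicates 1 (2.03) and 4 (1.17). Layer 4 cortex genes had a median of -0.07, with Cux1 and Whrn called lowered and 2 raised and 2 lowered when adjusted over the list alone.

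Lower parvalbumin markers, with a median change in log2 CPM of -0.142 in homozygotes, were set against 3 explanations. Excitatory markers had a median of -0.0164 (95% bootstrap interval over genes -0.0803 to 0.018), and that interval holds no spread between libraries. Their score was -0.712 and -0.863 in homozygous replicates 1 and 2, so less neuronal tissue stays open there. In the other homozygous libraries it was -0.005 to 0.3, within the wild-type range of -0.187 to 0.377. These values argue against less neuronal tissue in those libraries. The 21 other GABAergic markers had a median of 0.0685 (-0.0366 to 0.135), without the fall that fewer interneurons of every class would give. That list shares Dlx genes with the neuroblast list. The score of all 24 GABAergic markers was 0.478, 0.452 and 0.429 in homozygous replicates 2, 5 and 8, and -0.596 to 0.182 in the others. Those replicates also had the highest olfactory scores (1.23, 1.61 and 1.83). Olfactory tissue could hide a fall and the interval holds no spread between libraries, so the test cannot decide. A shift of the dissected piece away from layer 4 stays open, with a median of -0.0728 (-0.161 to 0.236) over 8 genes. A lower level of these transcripts, or fewer of these cells, may follow from the genotype, and neither was tested.

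Higher neuroblast genes may come from more ventricular wall or olfactory tissue in some homozygous pieces. With the ependymal score as a covariate the list's median changed from 0.265 to 0.206 (0.0975 to 0.279), and with the olfactory score to 0.256 (0.0865 to 0.31). Both intervals reach below the bound set for excluding the explanation, so neither tissue is excluded. An effect of the genotype on these cells stays open beside them.

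Lower glucocorticoid-induced genes were set against the hour of collection and handling. With a clock phase score as a covariate the median of the 26 genes outside that score was -0.371 (-0.459 to -0.187), against -0.31 without it, and with the immediate early gene score the median of the 27 genes was -0.31 (-0.442 to -0.178), against -0.289. Neither score clearly differed between homozygotes and wild type (exact permutation p = 0.192 for clock phase and 0.356 for immediate early genes). The clock phase score was 0.432 ± 1.63 in wild type (SD, n = 6) and -0.62 ± 1.22 in homozygotes (SD, n = 8), so a difference is not excluded. The intervals are over genes and not libraries. So these tests do not decide on the hour of collection or handling. Stress hormone levels, housing and order of collection are not given in the sources used here, and with the genotype they stay open.

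Other splits of the same libraries, 100 for each comparison with the real one included, showed which counts chance can give. For homozygous against wild type 1 split, the real one, gave as many as 261 genes, with 4 the highest of the others. For the trend 1 gave as many as 306, with 105 the highest of the others. Chance is thus unlikely for both, although 1 of 100 is the smallest share that these splits can give. The splits do not tell an effect of the genotype from a tissue difference that goes with it. For homozygous against heterozygous 2 splits gave at least 18 genes, a share under the limit of 0.05, but the other of them called 167. So many genes in a split that does not follow genotype point to a structure of the samples, and what that split separates was not tested, so the 18 genes are less secure than that share alone would show. For heterozygous against wild type 52 splits gave at least 532 genes at an unadjusted p under 0.05, the highest other 2716, and for the midpoint 63 gave at least 573, the highest other 2932, so chance cannot be excluded. The same holds for the lists called with the preset correlation: 46 splits gave at least 11 lists in homozygous against wild type (highest other 22), 57 at least 7 in heterozygous against wild type (15) and 25 at least 14 in homozygous against heterozygous (19). It holds also for long genes, where 5 splits gave an absolute median change of at least 0.02301 (highest other 0.02833).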
